A study of Mus musculus with 28 samples.

How the data were processed

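The series holds 28 Affymetrix HT MG-430 PM arrays of mouse T-lineage acute lymphoblastic leukemia (T-ALL). Each array carried bone marrow RNA extracted with Trizol, and 100 ng of total RNA was amplified with the 3' IVT Express kit and labeled with biotin, per the labels. The deposited values are log2 expression values made by the authors with RMA (robust multi-array average), per the submitters' processing notes. The software that ran RMA, its version and any filter on probe sets are not given in the sources used here. Array medians lay between 3.46 and 3.56 and upper quartiles between 5.73 and 6.26. The values were used as deposited, with other scalings among the alternatives. RMA adjusts array distributions to each other, so a shift of all genes in one group could not be seen in these values. Arrays give no counts, and their number limits the precision. All 28 columns were used.

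Probe sets were named from the platform annotation that came with the series. Of 45141 probe sets, 28898 had 1 gene symbol, 551 had several and 15692 were not listed, 104 of the latter being Affymetrix controls. Symbols were compared with a RefSeq gene table through Entrez identifiers, which left 209 symbols unmatched and changed none. A gene was represented by its probe set with the highest mean over all arrays, giving 17097 genes. Genes were kept when their third-highest value reached the median of all values, 3.50, which left 11282 genes. Kras, Pten, Il7r, Tcf7 and Shq1 have no probe set listed by the annotation used and are not named here by a value.

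The labels name the leukemia of every array, and that name pairs parental with resistant samples. Samples of one leukemia deviated together from their group means: the correlation of deviations lay between 0.386 and 0.760 in all 8 leukemias. The leukemia was therefore the replicate and a fixed block. Arrays of one leukemia and group were averaged first, giving 19 values, and limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) fitted groups and leukemias with 9 residual degrees of freedom. This fit gave GDC-0941-resistant against parental, combination-resistant against parental, and the difference between regimens. Resistance of either regimen was tested with 2 values per leukemia, the parental mean and the mean of its regimen means, with 7 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 11282 genes, with a threshold of 0.05. Changes are log2 differences, resistant minus parental, with the standard error (SE) of the fit.

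A further limma fit used all 28 arrays with 1 mean per leukemia and group, and gave the change within each leukemia and a moderated F test of differences between leukemias. Arrays are the replicates of that fit, with 9 residual degrees of freedom, and a lone array was assumed to vary like repeated ones. Nothing in the labels says whether repeat arrays came from separate animals, so its p-values measure only a spread between arrays that may be technical.

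Before the data were examined, the comparisons, the alternatives, the named genes and 25 gene lists were fixed. The lists were Notch targets, ribosome biogenesis, FOXO targets, components of the PI3K-AKT-mTOR pathway, MAPK output genes, RAS-RAF components, proliferation, cholesterol and lipid synthesis, glycolysis, ATF4 targets, interferon response, p53 targets, BCL2 family and inhibitors of apoptosis, drug efflux, growth factor and cytokine receptors, progenitor and early T-cell markers, double-positive thymocyte markers, effector T and NK genes, T-cell receptor signaling, and markers of B cells, granulocytes, macrophages, erythroid cells, megakaryocytes, and stroma with endothelium. They were written from textbook knowledge, and 420 of the 476 genes in the lists and among the fixed genes had a listed probe set. Some genes, such as Ptcra, Kit, Il2ra and Pmaip1, stand in more than 1 list. The mean change of a list in each leukemia was tested with exact two-sided sign flips over leukemias, adjusted over the 25 lists. Beside it stand camera with a preset correlation of 0.01 and with an estimated correlation, and fry, all from limma. Camera compares the list with the other genes; fry tests whether the list's genes move one way on balance. Combination-resistant leukemia was measured in 5 leukemias, where exact flips cannot give a p below 0.0625.

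Genes named in the text were Notch1, Myc, Pik3r1, Dtx1 and Hes1 always. For each comparison the 10 largest changes each way past the threshold were to be named, and where fewer than 5 passed, the 5 smallest p-values each way. For each list, up to 4 members that passed or the 2 with the smallest p were named. Clone, Gm and LOC names were counted, not named, except where a count under an alternative rests on them. Genes outside this rule are said to have been chosen after their values were seen.

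The fits were tested on simulated data of the same design with 50 genes changed at each of 4 sizes. For resistance of either regimen, log2 changes of 0.585, 1, 2 and 3 were recovered in 46%, 80%, 100% and 100% of genes, with 6 false calls. For GDC-0941-resistant against parental the shares were 42%, 76%, 100% and 98%, with 7 false calls. For combination-resistant against parental they were 26%, 76%, 100% and 98%, with 9 false calls. The planted changes were equal in both regimens, so for the difference between regimens the simulation measured only false calls, of which there were 0. Each planted change was also equal in all leukemias, all sizes were planted together, and noise was drawn for each gene on its own. The recovered shares therefore do not give the power for real changes that vary between leukemias or are few.

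RNA quality was measured as the 3' minus 5' difference of the Actb and Gapdh control probe sets. The correlation between the regimens' changes was set beside 100 simulated unchanged groups sharing the same parental arrays. The alternatives were no leukemia block, all 28 arrays with a fixed or random block, other probe set rules, no filter and a stricter filter at 6.16, fits without trend or with robust variance, quantile normalization, median centering, array weights, a minimum log2 change of 1, an RNA quality covariate, separate fits, and each leukemia left out. Added after seeing the data were the granulocyte list as a covariate, omission of the combination-resistant array of leukemia 73A with and without leukemia 5C, exact sign flips of the fixed genes with all leukemias or without 5C, and the RNA quality change without 5C. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.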

Results

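Expression was measured in bone marrow samples of 8 mouse T-ALLs, cancers of immature T cells, after treatment in vivo with GDC-0941, an inhibitor of PI3 kinase, alone or with PD0325901, an inhibitor of the kinase MEK. Leukemia 8633 was wild type for Kras, and the other 7 carried Kras G12D, an activating mutation of this signaling GTPase. There were 11 arrays of parental leukemia from all 8 leukemias, 10 arrays of GDC-0941-resistant leukemia from 6, and 7 arrays of leukemia resistant to the combination from 5. The labels name a drug only for the resistant groups. Effects of drug exposure and of resistance therefore cannot be told apart in the comparisons with parental leukemia. The 3 leukemias 73A, 2M and 10M had samples of both regimens. Over all genes tested, pairs of arrays correlated between 0.892 and 0.991, and 25 of 28 arrays matched best with another array of the same leukemia. The combination-resistant array of 73A did not: its best match was a parental array of 10M, at 0.949, the lowest best match of all arrays. The others were resistant arrays of 2M. A GDC-0941-resistant one matched best with a GDC-0941-resistant array of 20M, at 0.978. A combination-resistant one matched best with the combination-resistant array of 10M, at 0.976.

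The arrays differed widely in granulocyte transcripts. The mean of 15 granulocyte markers ranged from 3.72 to 10.90 on the log2 scale, with S100a8, a calcium-binding protein of neutrophils, between 5.00 and 13.55 and Mpo, the myeloperoxidase of their granules, between 3.20 and 12.52. Between the 2 parental arrays of leukemia 10M alone this mean differed by 3.74. Several T-cell transcripts were steadier: the T-cell receptor signaling list lay between 8.15 and 9.43, Cd3g, a chain of the receptor complex, between 9.85 and 11.13, and Zap70, its kinase, between 8.49 and 9.61. Cd8a, a co-receptor, was not: it was at 5.07, 5.97 and 6.98 in the 3 arrays of JW81, and the highest array had 11.19. The combination-resistant array of 73A had the highest granulocyte mean, 10.90, against 3.72 and 4.12 in the parental arrays of 73A. Leukemia 5C stood apart in thymocyte genes in both its arrays. There Dtx1, a Notch target, was at 3.46 and 3.71, and Rag1, a recombinase of thymocytes, at 3.40 and 4.17, against means of 11.08 and 10.13 in the other arrays. Rag1 was also low in the parental array of JW81, at 5.43, with 7.24 and 8.37 in its resistant arrays. Hes1, another Notch target, was at 3.19 and 3.22 in 5C and at 7.52 or more in the others, and Ptcra, the pre-T-cell receptor chain, at 2.47 and 2.58 against 6.99 or more. The changes of Dtx1, Hes1 and Ptcra in 5C, -0.25, 0.03 and 0.11, were therefore measured near background.

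**Figure D1:**
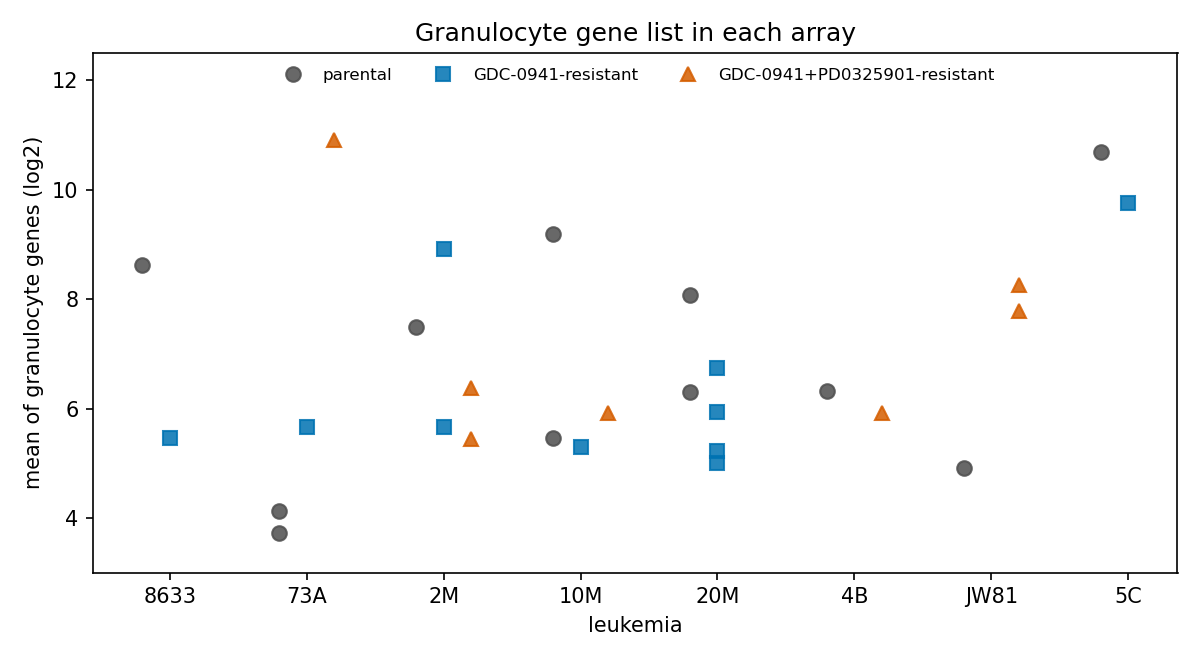
Mean log2 signal of 15 granulocyte markers in each of the 28 arrays, by leukemia, with parental arrays as circles, GDC-0941-resistant arrays as squares and combination-resistant arrays as triangles. Values ran from 3.72 in a parental array of 73A to 10.90 in the combination-resistant array of 73A.

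The series title concerns loss of oncogenic Notch1 in resistance to PI3 kinase inhibition, so Notch1 and its targets were followed first, with every leukemia counted once. The arrays measured Notch1 mRNA, not protein, and gave no separate value for an oncogenic form. Notch1, the receptor itself, was 1.34-fold lower in resistant than in parental leukemia (log2 change -0.43, SE 0.11, n = 8), lower in 8 of 8 leukemias. Leukemia 5C alone was at -1.30, and the mean of the other 7 was -0.30. Myc, a growth regulator downstream of Notch1, was 1.43-fold lower (-0.52, SE 0.10), and Notch3, a second receptor and Notch target, 1.38-fold lower (-0.47, SE 0.08), both in 8 of 8. Ptcra was lower in 7 of 8 (-0.66, SE 0.14), as was Dtx1, an E3 ligase of the pathway (-0.25, SE 0.07). Hes1, a transcriptional repressor induced by Notch, went the other way, higher in 6 of 8 (0.32, SE 0.13). Without 5C, where these 3 genes lay near background, Ptcra was lower in 7 of 7, Dtx1 lower in 6 of 7 and Hes1 higher in 5 of 7.

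None of these genes passed limma's adjustment over 11282 genes, with adjusted p between 0.166 for Notch3 and 0.374 for Hes1. Exact sign flips over the 8 leukemias, chosen after seeing the data and adjusted over the 5 fixed genes, gave adjusted p = 0.0195 for Notch1 and Myc (unadjusted 0.00781, the smallest such flips can give), 0.0260 for Dtx1 and 0.107 for Hes1. Without leukemia 5C, also chosen after seeing the data, exact flips over 7 leukemias gave adjusted p = 0.0391 for Notch1 and Myc, 0.0521 for Dtx1, which no longer passed, and 0.117 for Hes1. Pik3r1, the regulatory subunit of PI3 kinase, had a change of 0.00 (SE 0.11) and an exact p of 1, and its other 3 probe sets gave 0.15, 0.31 and 0.23. The second probe sets of Notch1 and Notch3 gave -0.55, lower in 7 of 8 leukemias, and -0.65, lower in 8 of 8.

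**Figure D2:**
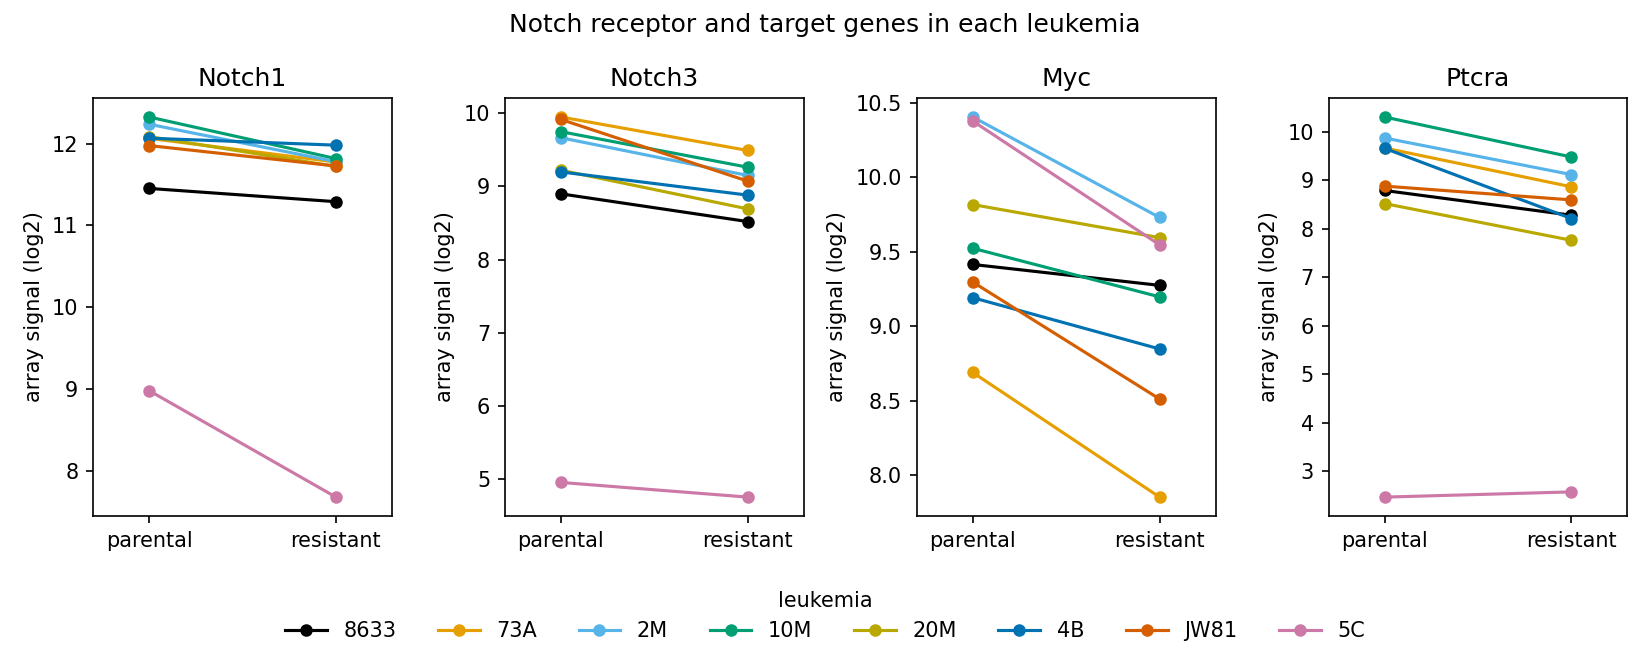
Log2 array signal of Notch1, Notch3, Myc and Ptcra in parental and resistant samples, with 1 line per leukemia joining the mean of its parental arrays to the mean of its resistant regimens. Notch3 and Ptcra were not among the fixed genes. The fixed Notch targets Dtx1 (mean change -0.25) and Hes1, which went the other way (0.32), are not shown. Notch1, Notch3 and Myc were lower in resistant samples of 8 of 8 leukemias and Ptcra in 7 of 8, with 5C near background as the exception, and leukemia 5C lay far below the others in Notch1, Notch3 and Ptcra.

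The Notch target list, with 17 measured members, had a mean change of -0.23 (SD 0.22, n = 8) and a member median of -0.13. It was lower in 8 of 8 leukemias, although leukemia JW81 alone was at -0.70 and the mean without it was -0.16. In JW81 the member Il2ra was at -5.84. In 5C, where Dtx1, Hes1 and Ptcra lay near background, the list went from 5.10 to 4.86. By sign, 12 members were lower and 5 higher. Adjusted over the list alone, 5 members were lower and 1 higher, against 0 over all genes tested. Its exact sign-flip p was 0.00781, or 0.0977 adjusted over 25 lists. Camera gave adjusted p = 0.00400, which was lost at adjusted p = 0.139 with an estimated correlation, and fry gave adjusted p = 0.0246. Markers of double-positive thymocytes, the stage that bears both CD4 and CD8, were lower in 7 of 8 leukemias with a list mean of -0.28 (SD 0.21). Their examples were Ptcra and Themis, a T-cell selection factor (-0.37, SE 0.07, lower in 8 of 8). Of its 14 members 11 were lower, 4 of them adjusted over the list alone. The exact p was 0.0234, or 0.195 adjusted, camera gave adjusted p = 2.15e-04 and 0.0873 with an estimated correlation, and fry 0.0246. Granulocyte markers went both ways beside these groups, with a mean of -0.14 (SD 2.55), a median of 0.01, and lower values in 6 of 8 leukemias, and the mean was 0.30 without 8633 and -0.78 without 73A.

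FOXO targets, genes that this transcription factor induces when PI3 kinase signaling is low, were higher in 7 of 8 leukemias (list mean 0.22, SD 0.22). They included Cited2, a transcriptional co-regulator (0.45, SE 0.09, higher in 8 of 8), and Sesn1, a stress-induced inhibitor of mTOR signaling (0.29, SE 0.08). Adjusted over the list alone, 4 of 14 members were higher and 1 lower. The exact p was 0.0391, or 0.195 adjusted, and camera's adjusted p of 0.0389 became an adjusted p of 0.556 with an estimated correlation. Whether the inhibitor was still acting in the resistant samples was not tested. Components of the PI3K-AKT-mTOR pathway were lower in 6 of 8 (list mean -0.12, SD 0.13, 18 of 24 members lower), such as Foxo3 (-0.31, SE 0.10) and Pdpk1, the kinase that activates AKT (-0.14, SE 0.06). This list had an exact p of 0.0391, or 0.195 adjusted, and camera's adjusted p of 0.0274 became an adjusted p of 0.452 with an estimated correlation. Stroma and endothelium markers, 5 genes such as Cxcl12 (-0.26, SE 0.09), were lower in 8 of 8 leukemias with a mean of -0.10 (SD 0.09, exact p 0.00781, 0.0977 adjusted, fry adjusted p = 0.0498, camera adjusted p = 0.270).

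Dusp1, a phosphatase of MAP kinases, had the smallest p of any gene and was 1.59-fold higher (0.67, SE 0.09, 8 of 8, adjusted p = 0.1004). Fos and Ier2, early response genes, were higher by 0.46 (SE 0.11, 7 of 8) and 0.68 (SE 0.16, 8 of 8). The MAPK output list that holds Fos and Ier2 had a mean of 0.12 (SD 0.29, exact p 0.289, 2 members higher adjusted over the list alone). Other genes higher in 8 of 8 were Atg14, an initiator of autophagy (0.81, SE 0.14), Spty2d1, a histone chaperone (0.56, SE 0.09), Ing2, a chromatin reader (0.55, SE 0.09), and Tuba1a, an alpha tubulin (0.46, SE 0.08). Lower in 8 of 8 were the long noncoding RNAs Mirt1 (-0.72, SE 0.13) and Kcnq1ot1 (-0.70, SE 0.13), Rnf213, a large ubiquitin ligase (-0.64, SE 0.11), and Thoc2, a subunit of an mRNA export complex (-0.29, SE 0.05). With Notch3, these were the genes named for the smallest p in each direction, none past the threshold, with adjusted p between 0.1004 and 0.178.

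Survival genes differed in direction. Mcl1, which protects cells from apoptosis, was higher in 8 of 8 leukemias (0.21, SE 0.05), while Bcl2l1, another protector, was lower in 8 of 8 (-0.32, SE 0.10). The BCL2 family list had a mean of 0.01 and a median of -0.00, which differ in sign, and 1 of 18 members was higher adjusted over the list alone. Among p53 targets (mean 0.09, median -0.03 and camera's direction lower), Zmat3 was lower in 8 of 8 (-0.41, SE 0.13) and Bbc3, which promotes cell death, higher in 6 of 8 (0.54, SE 0.20). Glycolysis genes had a mean of 0.08, with Pgk1 (0.26, SE 0.08, 8 of 8) and Tpi1 (0.37, SE 0.11, 7 of 8) higher. Cholesterol genes had a mean of 0.04 with 1 member higher adjusted over the list alone, and included Stard4, a sterol carrier (0.50, SE 0.12, 8 of 8), and Ebp, a sterol isomerase (0.30, SE 0.11, 7 of 8), although 5C stood apart in both at 1.21 and 1.03. ATF4 targets had a mean of 0.13 with Ddit4, an inhibitor of mTOR signaling, at 0.57 (SE 0.22). Proliferation genes had a mean of 0.04, although Uhrf1 (-0.20, SE 0.06) and Top2a (-0.16, SE 0.05), both used in DNA replication, were lower in 7 of 8.

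Growth factor and cytokine receptors had a mean of -0.14, with Kit, the stem cell factor receptor (-0.78, SE 0.26), and Insr, the insulin receptor (-0.39, SE 0.13), lower in 7 of 8. The T-cell receptor signaling list had a mean of 0.00 against a median of -0.08 and a lower direction in camera, with Lat, an adaptor of the receptor, lower in 8 of 8 (-0.16, SE 0.05) and Nr4a3, a gene induced by receptor signals, higher in 6 of 8 (1.03, SE 0.31). Progenitor markers had a mean of -0.05 and a median of 0.01, RAS-RAF components a mean of -0.06 with Rasa2, an inhibitor of RAS, at -0.36 (SE 0.11), and drug efflux genes a mean of -0.05 and a median of 0.01. Ribosome biogenesis genes had a mean of 0.02, interferon response genes 0.06, and effector T and NK genes -0.07. Markers of other cell types had means of -0.18 for B cells, -0.10 for macrophages, including C1qa, a complement chain (-0.31, SE 0.13), -0.26 for erythroid cells and -0.09 for megakaryocytes. Many of these small means rested on 1 leukemia. Without JW81 the mean was -0.07 for erythroid markers, -0.08 for receptors, 0.02 for effector T and NK genes, 0.07 for MAPK output and 0.01 for p53 targets, and C1qa was at -0.20. Macrophage markers were at -0.02 without 8633 and -0.21 without 73A, ATF4 targets at 0.06 without 10M, and B-cell and megakaryocyte markers at -0.11 and 0.03 without 5C. With each leukemia left out in turn, the mean ran from -0.11 to -0.02 for RAS-RAF components, -0.14 to 0.00 for drug efflux and for progenitor markers, 0.01 to 0.06 for proliferation, 0.02 to 0.07 for cholesterol genes, 0.05 to 0.12 for glycolysis, 0.04 to 0.11 for interferon response, -0.03 to 0.07 for ribosome biogenesis, -0.01 to 0.03 for the BCL2 family and -0.04 to 0.05 for T-cell receptor signaling. Apart from the Notch, thymocyte, FOXO, PI3K and stroma lists, no list had an exact adjusted p below 0.635 or a camera adjusted p below 0.136.

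With limma, 0 genes passed the threshold for resistance of either regimen, while 1361 had an unadjusted p under 0.05 (716 higher, 645 lower) against 564 by chance. With labels swapped within leukemias, up to 1299 genes had such a p, so 564 is a weak yardstick. Over 25 alternatives the count past the threshold ranged from 0 to 13. It was 0 without the combination-resistant array of 73A and without that array and leukemia 5C, settings chosen after seeing the data. Array quality weights called 13 genes, among them Dusp1, Notch3, Ptcra and Cited2.

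**Figure D3:**
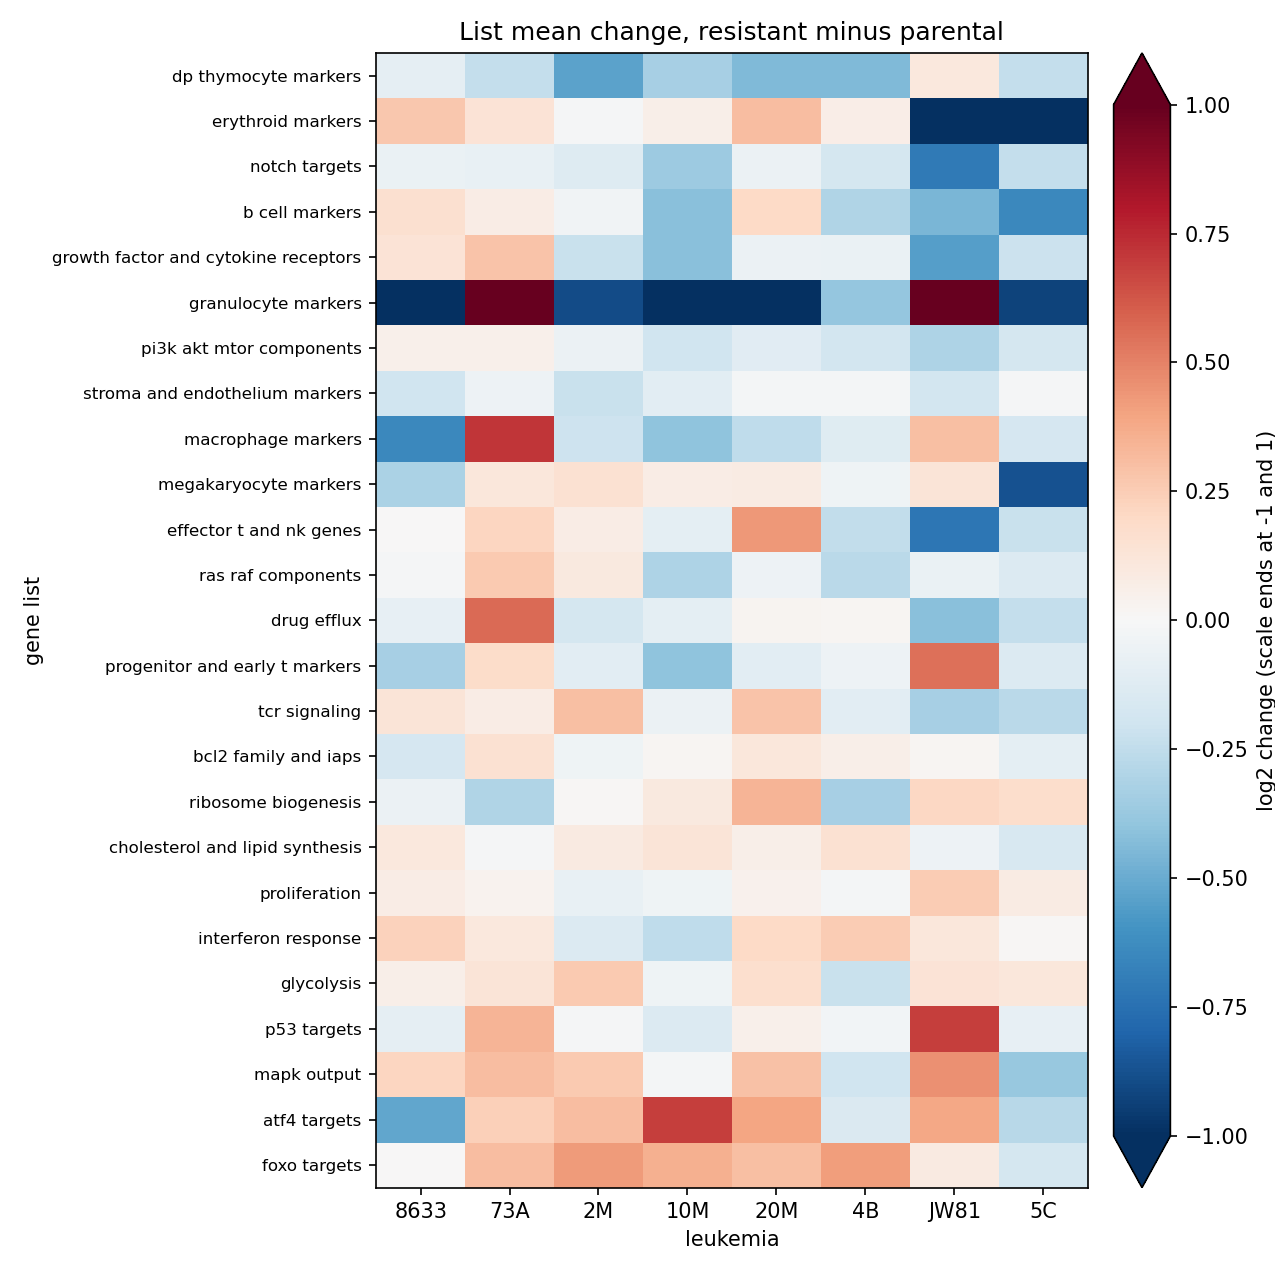
Mean log2 change of each gene list (vertical axis) in each of 8 leukemias (horizontal axis), resistant minus parental, with red for higher and blue for lower in resistant samples and a color scale that ends at -1 and 1. Notch targets were lower in all 8 leukemias, whereas granulocyte markers ran from -3.17 in 8633 to 4.36 in 73A.

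Resistance to GDC-0941 alone was measured in 6 leukemias. Notch1 (-0.39, SE 0.14), Myc (-0.47, SE 0.16) and Notch3 (-0.28, SE 0.09) were lower in 6 of 6. Apart from leukemia 5C, where both lay near background, Dtx1 was lower in 5 of 5 (-0.18 with 5C, SE 0.07) and Hes1 higher in 5 of 5 (0.37 with 5C, SE 0.22, but 0.19 without 73A). The fitted change of Notch1 was -0.22 without leukemia 5C, which was at -1.30. Nr4a3, a nuclear receptor induced by T-cell receptor signals, was 2.82-fold higher in 6 of 6 (SE 0.38 on the log2 scale). Klf11, a transcription factor of the TGF-beta response, was 2.01-fold higher (1.01, SE 0.21), and Tgfbr2, a TGF-beta receptor, was higher by 0.47 (SE 0.13), both in 6 of 6. Granulocyte markers were lower in 5 of 6 leukemias beside them (list mean -1.01, SD 1.68), such as Mpo (-2.14, SE 1.37) and Fcnb (-1.16, SE 0.57). With each leukemia left out in turn, the list mean ran from -1.56 to -0.57, the latter without leukemia 8633.

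The other genes with the smallest p-values were Seh1l, a nuclear pore subunit (0.75, SE 0.15), Slc30a1, a zinc exporter (0.85, SE 0.20), Atg14 (0.84, SE 0.19) and Spty2d1 (0.61, SE 0.14), all higher in 6 of 6. Rnf213 (-0.52, SE 0.12), Kmt2d, a histone methyltransferase (-0.50, SE 0.13), Stambpl1, a deubiquitinase (-0.43, SE 0.11), Parvg, an adhesion protein (-0.36, SE 0.10), and Thoc2 (-0.22, SE 0.06) were lower in 6 of 6. All had limma adjusted p = 0.825. Exact sign flips over the 6 leukemias, chosen after seeing the data, gave p = 0.0313 for Notch1 and Myc, the smallest they can give, or 0.0391 adjusted over the 5 fixed genes, with mean changes of -0.44 and -0.48. Dtx1 and Hes1 had the same p, but only by counting 5C. Without 5C, exact flips over 5 leukemias cannot reach 0.05, and Notch1, Myc, Dtx1 and Hes1 all had an adjusted p of 0.0781, with mean changes of -0.27, -0.41, -0.13 and 0.51.

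The Notch target list was lower in 6 of 6 leukemias (mean -0.15, SD 0.17, but -0.09 without 10M), with 14 of 17 members lower and Fjx1, a secreted kinase, among the 3 higher (0.42, SE 0.14). Double-positive thymocyte markers were lower in 6 of 6 (mean -0.25, SD 0.12, 12 of 14 members lower), such as Themis (-0.32, SE 0.09) and Ptcra (-0.47, SE 0.17, lower in 5 of 5 apart from 5C). FOXO targets were higher in 5 of 6 (mean 0.26, SD 0.29, 12 of 14 members higher), such as Cited2 (0.41, SE 0.13) and Fbxo32, a ubiquitin ligase of muscle atrophy (0.63, SE 0.22), while Foxo3 itself was lower in 5 of 6 (-0.35, SE 0.11). Fos (0.39, SE 0.13) and Ier2 (0.57, SE 0.21) were higher in 6 of 6. Camera's adjusted p was 0.00275 for the Notch list, 0.00265 for thymocyte markers, 0.00265 for FOXO targets, 0.00275 for granulocyte markers and 0.0445 for macrophage markers (mean -0.27). With an estimated correlation these became adjusted p = 0.135, 0.135, 0.352, 0.655 and 0.352. The exact adjusted p was 0.195 for the Notch, thymocyte and macrophage lists, 0.391 for FOXO targets and higher still for granulocyte markers, and fry called 0 lists. Adjusted over the list alone, 0 members passed in these 5 lists, and 1 member of the T-cell receptor signaling list was higher.

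With limma, 0 genes passed for GDC-0941 resistance in the joint fit and in all 26 alternatives, including those without leukemia 5C and the combination-resistant array of 73A. There were 672 genes at an unadjusted p under 0.05 (435 higher, 237 lower) against 564 by chance and up to 673 with labels swapped within leukemias. List means differed in sign from camera's direction, which was lower, for T-cell receptor signaling (mean 0.10), glycolysis (mean 0.03, median -0.04) and effector T and NK genes (mean 0.03, median -0.02). With each leukemia left out in turn, these means ran from 0.06 to 0.17, from -0.01 to 0.07 and from -0.05 to 0.08.

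Resistance to GDC-0941 with PD0325901 was measured in 5 leukemias. Notch3 was 1.63-fold lower (-0.70, SE 0.10), Notch1 was lower by a log2 change of -0.47 (SE 0.15), and Ptcra was 1.91-fold lower (-0.93, SE 0.18), each in 5 of 5, while Myc (-0.61, SE 0.18) and Dtx1 (-0.34, SE 0.08) were lower in 4 of 5 and Hes1 higher in 3 of 5 (0.31, SE 0.24, but -0.01 without leukemia 2M). Rnf157, a ubiquitin ligase, was 2.64-fold lower (-1.40, SE 0.21) and Gimap6, a GTPase of lymphocyte survival, 1.56-fold lower (-0.64, SE 0.10). Bcl2, which protects lymphocytes from apoptosis, was 1.53-fold lower in 5 of 5 (-0.61, SE 0.13). Msra, which repairs oxidized methionine, was 1.91-fold higher (0.93, SE 0.14), Dusp1 1.80-fold higher (0.85, SE 0.15), and Herpud1, a factor of protein degradation at the endoplasmic reticulum, 1.79-fold higher (0.84, SE 0.15), all in 5 of 5.

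The smallest adjusted p was 0.0507, shared by Notch3, Rnf157, Gimap6, Rnf213 (-0.79, SE 0.12) and Msra, and 49 genes had an adjusted p under 0.1. They included Ptcra and Bcl2 at 0.0991, Tuba1a at 0.0638 (0.71, SE 0.12), Tbrg1, a growth regulator, at 0.0717 (0.50, SE 0.09), Thoc2 at 0.0632 (-0.38, SE 0.06), Dusp1 at 0.0707 and Herpud1 at 0.0797. Klf2, a transcription factor of T-cell quiescence and a FOXO target, was 3.82-fold higher in 5 of 5 (1.93, SE 0.55, adjusted p = 0.233), but the change was 1.22 without leukemia 2M, and 4B and JW81 had 0.07 and 0.22. Kit, at -1.23 (SE 0.37), and Il2ra, the alpha chain of the interleukin-2 receptor, at -1.72 (SE 0.60), were lower in 5 of 5. The growth factor and cytokine receptor list they belong to had 11 members lower and 8 higher (mean -0.19, lower in 4 of 5, exact p 0.5, with a mean of -0.10 without JW81 and -0.38 without 73A). Leukemia JW81 alone had Il2ra at -5.84, and the fitted change without it was -0.79. Granulocyte markers were higher beside these genes by a list mean of 1.34 (SD 3.67), higher in 2 of 5 leukemias, 73A and JW81, and lower in 3, with S100a9 at 1.66 (SE 1.12) and Mmp8 at 1.47 (SE 0.81). These rested on 73A: without it the list mean was -0.07, and S100a9 and Mmp8 were at 0.29 and 0.19.

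The Notch target list was lower in 5 of 5 leukemias (mean -0.29, SD 0.24, member median -0.08), with 6 of 17 members lower adjusted over the list alone. Without leukemia JW81, where the member Il2ra was at -5.84, the list had a mean of -0.19. Its camera adjusted p of 0.0135 became an adjusted p of 0.142 with an estimated correlation, and fry gave adjusted p = 0.0170. Double-positive thymocyte markers were lower in 4 of 5 (mean -0.36, SD 0.32), with Themis at -0.41 (SE 0.10) and 4 of 14 members lower adjusted over the list alone. Camera gave adjusted p = 9.69e-05, 0.0939 with an estimated correlation, and fry 0.0170. Components of the PI3K-AKT-mTOR pathway were lower in 4 of 5 (mean -0.16, SD 0.15, 19 of 24 members lower), such as Inpp4b, a lipid phosphatase (-0.73, SE 0.28, but -0.39 without 10M), and Pdpk1 (-0.18, SE 0.07). Camera's adjusted p of 0.0151 became an adjusted p of 0.142 with an estimated correlation, and fry gave 0.0224. FOXO targets had a mean of 0.26 (SD 0.16, higher in 5 of 5) against a median of -0.02, with 3 members higher adjusted over the list alone, with Cited2 as another member (0.54, SE 0.14). The MAPK output list had a mean of 0.12 and a median of -0.03, with 4 members higher and 3 lower adjusted over the list alone, and its mean ran from 0.03 without JW81 to 0.20 without 4B. Fos (0.61, SE 0.14, 4 of 5) and Ier2 (0.86, SE 0.23, 5 of 5) were higher. Mean and median also differed in sign for interferon response genes (-0.01 and 0.07), RAS-RAF components (-0.03 and 0.01, 1 member lower adjusted over the list alone) and the BCL2 family (0.01 and -0.05, 1 member lower adjusted over the list alone). With each leukemia left out in turn, these means ran from -0.07 to 0.05, from -0.13 to 0.04 and from -0.04 to 0.04.

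Camera's adjusted p was also under the threshold for glycolysis genes (mean 0.16, such as Tpi1 at 0.62 and Pgk1 at 0.35, SE 0.19 and 0.10), for ATF4 targets (mean 0.34) and for cholesterol genes (mean 0.14), all higher, with 2, 0 and 1 members higher adjusted over the list alone. With 1 leukemia left out these means went down to 0.08 (without 73A), 0.21 (without 10M) and 0.06 (without 10M). It was under the threshold for T-cell receptor signaling (mean -0.05, but -0.17 without 2M and 0.02 without JW81, 4 members lower and 1 higher adjusted over the list alone), such as Nfatc1, a transcription factor it activates (-0.56, SE 0.13), and Lcp2, an adaptor (-0.35, SE 0.10), both lower in 5 of 5. It was also under the threshold for B-cell markers (mean -0.28) and granulocyte markers. With an estimated correlation these became adjusted p = 0.517 for glycolysis, 0.772 for ATF4 targets, 0.772 for cholesterol genes, 0.517 for T-cell receptor signaling, 0.322 for B-cell markers and 0.772 for granulocyte markers. No exact adjusted p lay below 0.521.

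With limma, 0 genes passed for combination resistance, while 1270 had an unadjusted p under 0.05 (540 higher, 730 lower) against 564 by chance. With labels swapped within leukemias, up to 1352 genes had such a p, more than in the real grouping. Alternatives gave 0 to 73 genes past the threshold: 73 with all 28 arrays and leukemia as a fixed block, 19 with the stricter filter, and 0 without the combination-resistant array of 73A and without that array and leukemia 5C, settings chosen after seeing the data. Without the leukemia block the changes turned in sign for Notch1 (0.08), Notch3 (0.08), Ptcra (0.20) and Dtx1 (0.69). That fit compares unlike sets of leukemias. The parental array of 5C was low in these genes, at 8.98, 4.96, 2.47 and 3.71, and 5C has no combination-resistant array.

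The difference between the regimens was tested directly, combination-resistant minus GDC-0941-resistant, with 3 leukemias carrying both. Mapre2, a microtubule-binding protein, was 4.14-fold higher after the combination (2.05, SE 0.40), and Msra (0.77, SE 0.16), Anxa2, a membrane-binding annexin (0.73, SE 0.18), Syngr2, a vesicle protein (0.72, SE 0.17), and Acadl, an enzyme of fatty acid oxidation (0.64, SE 0.16), were higher as well. Rgs1, an inhibitor of G-protein signals, was 2.91-fold lower (-1.54, SE 0.34), Rnf157 2.42-fold lower (-1.27, SE 0.24) and Bcl2 1.70-fold lower (-0.77, SE 0.14), followed by Apol7b (-0.65, SE 0.15) and Ppm1b, a phosphatase (-0.45, SE 0.09). In the MAPK output list, which follows the pathway that PD0325901 inhibits, the members with the smallest p were Dusp4, a phosphatase (-0.75, SE 0.25, but -0.41 without 73A), and Spry4, a feedback inhibitor (-0.59, SE 0.22, but -0.31 without 73A), both at limma adjusted p = 0.954. That list had 7 members higher and 10 lower (mean -0.07). Notch3 (-0.42, SE 0.11) and Trib2, a Notch target (-0.45, SE 0.15), were lower. Notch1 (-0.08, SE 0.17), Myc (-0.14, SE 0.20), Dtx1 (-0.16, SE 0.09), Hes1 (-0.06, SE 0.28) and Pik3r1 (-0.03, SE 0.15) lay near 0. With each leukemia left out in turn, Notch1 ran from -0.20 to 0.06, Myc from -0.44 to 0.01 and Hes1 from -0.49 to 0.13. Granulocyte markers were higher after the combination, by a list mean of 2.03 in 15 of 15 members, such as Mmp8 (1.84, SE 0.91) and Fcnb (1.41, SE 0.69), but without leukemia 73A these 2 were at 0.47 and 0.54.

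Camera's adjusted p was 1.08e-08 for granulocyte markers, 7.90e-04 for cholesterol genes (mean 0.20, 17 of 19 members higher, such as Msmo1, a sterol oxidase, at 0.50, SE 0.19), 0.00137 for glycolysis (mean 0.21, such as Aldoa at 0.72, SE 0.27, or 0.28 without 73A), 0.0405 for progenitor markers (mean 0.30) and 0.0133 for T-cell receptor signaling (mean -0.13, 17 of 21 members lower, such as Nfatc1 at -0.57 and Lcp2 at -0.33, SE 0.15 and 0.12). With an estimated correlation the adjusted p was 0.357 for each of these 5 lists. The Notch target list had a mean of -0.09 with camera adjusted p = 0.279, and 1 member was lower adjusted over the list alone, as was 1 member each of the BCL2 family and the B-cell markers. Mean and median differed in sign for interferon response genes (-0.06 and 0.01), drug efflux genes (0.02 and -0.09), erythroid markers (0.10 and -0.05) and stroma markers (-0.03 and 0.06). With limma, 0 genes passed in the joint fit, where the smallest adjusted p was 0.814, and in all 26 alternatives, where it was 0.301 with all 28 arrays and a fixed block, while 526 had an unadjusted p under 0.05 (206 higher, 320 lower) against 564 by chance. The 3 shared leukemias are too few for exact sign flips to reach the threshold.

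Across 11282 genes, the changes of the 2 regimens correlated at r = 0.290 (Spearman's rho 0.438), with a covariance of 0.0175. Unchanged groups simulated against the same parental arrays gave a mean r of 0.309 (highest 0.364) and a mean covariance of 0.0145 (highest 0.0179). The observed r and covariance thus lay below the highest simulated ones. No rho was taken from the simulated groups, so the observed rho has no such yardstick. Simulated noise was drawn for each gene on its own, so the spread of the simulated values may be too narrow. From leukemias that do not overlap, 8633, 20M and 5C against 4B and JW81, r was -0.0536, rho 0.0383 and the covariance -0.00685. Genes are not independent replicates, and these values describe the arrays at hand.

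Changes within single leukemias were tested against the spread between repeat arrays. Leukemias 8633, 4B and 5C had 1 parental and 1 resistant array each and JW81 had 1 parental array, so their calls used the spread of other leukemias, and the differing counts do not show that the leukemias differ. Leukemia JW81, resistant to the combination, had 268 genes past the threshold (73 higher, 195 lower), including lower Il2ra (-5.84, SE 1.10), Il1r1, an interleukin-1 receptor (-3.90, SE 0.41), Prf1, the perforin of cytotoxic cells (-3.33, SE 0.55), and Cd2, an adhesion molecule of T cells (-2.55, SE 0.54). Erythroid genes fell there in 3 of 9 members, Car2 (-3.07, SE 0.30), Slc4a1 (-2.60, SE 0.18) and Car1 (-1.13, SE 0.26). The erythroid list mean was 5.85 in the lone parental array of JW81, the highest of all arrays, against 4.25 and 4.29 in its resistant arrays. Ei24, a p53 target (4.46, SE 0.35), Phlda1 (3.56, SE 0.35) and Cd5l, a macrophage product (1.76, SE 0.34), rose. T-cell receptor signaling fell in 3 of 21 members, Cd2, Ptpn22 (-1.18, SE 0.18) and Fyn (-1.04, SE 0.22). Also lower were Etv5, a MAPK-responsive factor (-2.96, SE 0.68), Abcb1b, a drug efflux pump (-2.51, SE 0.40), and Pik3r5, a PI3 kinase subunit (-2.47, SE 0.48), and Oas2, an interferon response gene, rose by 1.25 (SE 0.29). Its granulocyte list was higher by 3.10 (SE 1.65).

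Leukemia 73A had 148 genes past the threshold (136 higher, 12 lower). Granulocyte genes led them, with 6 of 15 members higher, such as Camp (6.56, SE 1.40), S100a9 (6.34, SE 1.16), Ngp (6.24, SE 1.25) and S100a8 (5.88, SE 1.09). Single members of other lists rose too: Ier3, an early response gene (2.69, SE 0.46), Abcc1, a drug efflux pump (1.79, SE 0.30), Ccl3, a chemokine (1.75, SE 0.38), Rasgrp1, an activator of RAS (1.61, SE 0.22), Pmaip1, a promoter of apoptosis (1.54, SE 0.27), Rhou (1.34, SE 0.30), Pik3cb, a PI3 kinase catalytic subunit (1.28, SE 0.16), and Erbb3 (1.20, SE 0.19). Without its combination-resistant array, a setting chosen after seeing the data, 8 genes passed in 73A (7 higher, 1 lower).

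Leukemia 5C had 102 genes past the threshold (76 higher, 26 lower), with Pf4, a platelet factor (-2.15, SE 0.42), Car2 (-1.80, SE 0.35), Slc4a1 (-1.72, SE 0.21) and Tbx21, a factor of effector T cells (-1.31, SE 0.29), lower. The parental array of 5C had the highest 3' minus 5' differences of all arrays, 1.13 for Gapdh and 0.832 for Actb. It also had an erythroid list mean of 5.12, against 3.78 in the resistant array of 5C. In 4B, Hspa1b, a heat shock protein (4.44), Plagl1 (3.06), Mx1, an interferon response gene (2.45), and Kcnf1 (2.45) rose, and Bex1 (-2.15) and Xist (-1.68) fell. In 10M, Piwil2 (2.45) and Plagl1 (1.89) rose and Arntl2 (-3.10), Taf9b (-1.59), F13a1 (-1.42) and Ttyh2 (-1.41) fell. In 8633, the Kras wild-type leukemia, Mpzl2 (1.83), Wasf1 (1.65) and Rab34 (1.26) rose. Apart from Mx1, the genes named for 4B, 10M and 8633 were chosen after their values were seen.

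In 2M and 20M, limma called 0 genes, with 529 and 524 at an unadjusted p under 0.05, and other settings also called 0. The moderated F test, with arrays as replicates, called 142 genes for a change that differed between leukemias, and 93 without the combination-resistant array of 73A. The 3' minus 5' difference, a measure of RNA quality, had a mean change with resistance of -0.06 (SD 0.17, n = 8, exact p 0.469) for Actb and of -0.14 (SD 0.30, n = 8, exact p 0.188) for Gapdh. Leukemia 5C weighed most in both, at -0.39 and -0.83, and the means of the other 7 were -0.01 and -0.04.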

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

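The tests chosen only after the result was seen were the granulocyte covariate and the comparison with T-cell receptor genes for the Notch list, the comparison of the 2 parental arrays of 10M, the test of a common effect on granulocyte genes, and all 3 tests of leukemia 5C. The tests of RNA quality and the splits of the samples were planned.

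The Notch target list was lower in 8 of 8 leukemias, by -0.23 on average, and JW81 stood apart at -0.70 against -0.36 to -0.06 in the others for either regimen and -0.27 to -0.12 for the combination. Part of the value of JW81 came from 1 member, Il2ra, which was at -5.84 there. A shift in granulocyte share is argued against by the covariate, which left the change at -0.231 (SE 0.078), and one in RNA quality by the Actb covariate, which left it at -0.258 (SE 0.080). A lower share of leukemic T cells would lower T-cell receptor genes alike, but the mean of the Notch list lay below that list by -0.229 (SD 0.160, lower in 7 of 8, exact p 0.0156). The member medians lay closer, at -0.13 and -0.08, and 15 of 21 T-cell receptor members were lower. A lower share of T cells was therefore not excluded. A lower Notch program in resistant leukemia is a hypothesis these tests leave open, found and tested on the same arrays. The list did not pass the exact adjusted test.

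Granulocyte genes differed widely between arrays, from -3.17 in 8633 to 4.36 in 73A in the list's change. Whether granulocytes in the marrow samples account for this was left open: between the 2 parental arrays of 10M 15 of 15 members went the same way, against 58.6% of all genes, but that pair was picked for its gap of 3.74 in the list mean, which left little room for another outcome. RNA quality is argued against by the correlation of deviations with the Actb difference, r = -0.0805. A common effect of resistance cannot be told apart from sampling, because the lowest change, -3.17 (SE 1.91), lies within 2 SE of 0 while 73A was at 4.36 (SE 1.35). SD between repeat arrays of this list mean was 1.35.

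Leukemia 5C lacked signal of Dtx1 and Ptcra that all other arrays had, and of Rag1, which was also low, at 5.43, in the parental array of JW81. Dilution by granulocytes is argued against, since the 73A combination-resistant array, as rich in granulocyte transcripts, had each of the 3 genes at least 5.96 above both 5C arrays. One mislabelled array is argued against because 2 of 2 arrays of 5C show it. An absence of T cells is argued against because Cd3e, Cd3g and Zap70 lay at most 0.985 below the mean of the other arrays. These genes do not tell leukemic from normal T cells. The parental and resistant arrays of 5C also had signal of both Xist, at 12.21 and 11.52, and Y-linked Eif2s3y, at 6.76 and 6.33. The reason for this was not tested. A different origin or stage of this leukemia may remain as an untested explanation, and a swap of the whole leukemia with an outside sample was not tested.

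An outlying leukemia was found in 21 of 184 groups tested. Chance gives about 1 in 20 for a single group, but these groups are not independent. Comparisons share arrays, lists share genes, and some genes, such as Jchain, Iglv1 and Per1, were chosen after their values were seen. The count therefore does not show more outliers than chance. Leukemia 5C stood apart for Notch1 (-1.30, for either regimen and for GDC-0941), Stard4 (1.21), Ebp (1.03), Cxcl12 (-0.86), Per1 (-0.35) and megakaryocyte markers (-0.87), and in GDC-0941 resistance for MAPK output (-0.38), T-cell receptor signaling (-0.27), erythroid markers (-1.34) and Themis (-0.73). Leukemia 73A stood apart for drug efflux genes (0.57), Jchain (1.17) and Iglv1 (1.44). In GDC-0941 resistance 10M stood apart for proliferation (-0.30) and 20M for effector T and NK genes (0.43). In combination resistance JW81 stood apart for erythroid markers (-1.58) and Il2ra (-5.84), and 2M for Dtx1 (0.09).

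Of 114 named genes tested, 10 changed differently between leukemias by the moderated F test over arrays. Their adjusted p was 0.0276 for Hspa1b, 0.00926 for Pik3cb, 0.00349 for Phlda1, 0.00560 for Rasgrp1, 0.00156 for Mx1, 0.00153 for Ei24, 0.0140 for Erbb3, 0.00699 for Il1r1, 0.00149 for Car2 and 1.36e-04 for Slc4a1. All of these but Hspa1b had passed the threshold within single leukemias in the same fit over arrays and were named for that. Hspa1b was chosen after its values were seen. The 10 calls are therefore no independent test of a difference between leukemias. Over all genes tested, the same F test called 142.

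Splits of the samples swapped parental and resistant labels within leukemias, or the regimens among resistant samples. The count past the adjusted threshold was 0 in each comparison, so every split had to give as many and these counts decide nothing: 32 of 32 splits for GDC-0941 (highest other 0), 100 of 100 for either regimen (highest other 2), 80 of 80 for the regimen difference (highest other 1) and 16 of 16 for the combination (highest other 1). At an unadjusted p under 0.05, the real grouping for either regimen gave 1361 genes against at most 1299 in the other splits run (1 of 100). These splits were a sample of all possible ones, so a higher count among the rest cannot be ruled out. Chance was not excluded for GDC-0941, with 672 against 673 (2 of 32). For the combination the values were 1270 and 1352 (2 of 16), and 16 splits are too few for a share under 0.05. For the regimen difference, 59 of 80 splits gave as many as the real 526, so chance was not excluded. The highest split gave 1167, and why it did was not tested.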

How the results depend on the processing

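The tests chosen only after the result was seen were the granulocyte covariate, the settings without the combination-resistant array of 73A (with or without 5C), the exact sign flips of the fixed genes with all leukemias or without 5C, and the RNA quality change without 5C. With no leukemia block, 0 genes passed in each of the 4 comparisons, so leaving out the pairing changed no call, although unadjusted counts were 318 for GDC-0941, 440 for the combination, 140 for the difference and 522 for either regimen. GDC-0941 resistance and the regimen difference had 0 genes in all 26 alternatives. For combination resistance the count rose from 0 to 73 with all 28 arrays and a fixed block, 19 with the stricter filter, which tests fewer genes, 9 with array weights, 6 without trend, 4 with the mean of probe sets (Gm20740, Gimap6, Notch3 and Msra), 3 with robust variance (Gm20740, Notch3 and Rnf157), and 1 each with a random block (Tbrg1), the Actb covariate (Mettl6) and the granulocyte covariate (Jchain). For either regimen it was 13 with array weights, 1 with the stricter filter (Dusp1) and 1 with the granulocyte covariate (Jchain). Leaving out each leukemia gave 0 to 7 genes for the combination (7 without 4B, 1 without JW81), 0 to 2 for either regimen (2 without 73A), and 0 to 0 in the other 2 comparisons. The genes named here that the text did not name before were chosen after their values were seen. For these changes the cause was not tested. In combination resistance, adjusted p over the alternatives ranged from 0.0117 to 0.999 for Notch3 and from 0.00713 to 0.999 for Msra. The Notch list mean passed by camera for GDC-0941 (-0.15, adjusted p = 0.00275, range 0.00275 to 0.391), and by camera and fry for the combination (-0.29, 0.0135 and 0.0170, range 0.0135 to 0.781) and either regimen (-0.23, 0.00400 and 0.0246, range 0.00400 to 0.195). Camera with an estimated correlation gave it adjusted p = 0.135, 0.142 and 0.139 in these 3 comparisons, so camera's calls were lost. Without each leukemia in turn this mean lay between -0.18 and -0.09, -0.34 and -0.19, and -0.25 and -0.16. Lists past the threshold went from 0 to 5 for GDC-0941 with camera, to 9 with camera and 3 with fry for the combination, and to 4 with camera and 3 with fry for either regimen. With an estimated correlation camera called 0 lists in each, with smallest adjusted p = 0.135, 0.0939 and 0.0873. Without 5C the exact adjusted p of the fixed genes was 0.0781 for Notch1, Myc, Dtx1 and Hes1 in GDC-0941 resistance, and for either regimen 0.0391 for Notch1 and Myc and 0.0521 for Dtx1. The correlation of the regimens' changes turned from 0.290 to -0.0536 in leukemias that do not overlap, which share no parental arrays. Within 8633 the count was 8 with no filter. Without the combination-resistant array of 73A it was 8 in 73A, and 93 genes differed between leukemias. Of 134 results for named genes 17 turned in sign under some alternative, as did 32 of 75 list results. Other scalings moved the median change of all genes by no more than 0.1. Megakaryocyte markers had no member left under the stricter filter and have no value there. Genes near background, which the filter removes, were tested only with no filter.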

Other observations

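The genes named in this part, and the tests on them, were chosen only after their values were seen.

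Jchain and Iglv1, genes of antibody-producing cells, were lower in resistant samples of most leukemias. Jchain, which joins antibody chains, was 4.08-fold lower (-2.03, SE 0.42, lower in 7 of 8 leukemias, limma adjusted p = 0.178), and Iglv1, a light chain gene, 2.19-fold lower (-1.13, SE 0.33, 7 of 8, adjusted p = 0.254). Leukemia 73A went the other way in both, at 1.17 and 1.44. Without 73A the changes were -2.49 for Jchain (adjusted p = 0.00559) and -1.50 for Iglv1 (adjusted p = 0.0253). With granulocyte transcripts as a covariate Jchain had an adjusted p of 0.0295, and over all alternatives it ranged from 0.00559 to 0.9996, and for Iglv1 from 0.0253 to 0.9996. The fixed B-cell list had a mean of -0.18 (SD 0.32), with 7 of 7 members lower, and did not pass its test.

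For resistance of either regimen, no gene of this paragraph passed the threshold in the fit with 2 values per leukemia. Id1, an inhibitor of differentiation factors, was 2.16-fold higher (1.11, SE 0.24, 7 of 8, adjusted p = 0.188), Fosb 2.06-fold (1.04, SE 0.31, 7 of 8, adjusted p = 0.263), Rel, an NF-kappaB subunit, 1.95-fold (0.96, SE 0.22, 7 of 8, adjusted p = 0.194), Junb 1.59-fold (0.67, SE 0.18, 8 of 8, adjusted p = 0.2405) and Per1, a clock gene, 1.55-fold (0.63, SE 0.15, 7 of 8, adjusted p = 0.201). The fixed MAPK output list, a wider test of such genes, had an exact p of 0.289. With array weights the adjusted p was 0.0489 for Id1, Rel and Per1, and over all alternatives it ranged from 0.0489 to 0.9996 for each. Hspa1b, a heat shock protein, was 4.08-fold higher (2.03, SE 0.47, 7 of 8, adjusted p = 0.194), but ran from -0.09 in 2M to 4.44 in 4B.

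Sex-linked genes gave values outside any comparison. Xist, expressed from the inactive X chromosome, was at 6.42 and 4.74 in the parental and resistant arrays of 4B and at 11.52 or more in the others. Eif2s3y, a Y-linked gene, was at 6.76 and 6.33 in the parental and resistant arrays of 5C and at 4.57 or less in the others.

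Of 27270 probe sets tested, 8851 had no single listed gene, and limma called 0 of them in any comparison. The smallest adjusted p of the 4 comparisons was 0.0549. Of all 27270, an unadjusted p under 0.05 was reached by 1955 for GDC-0941, 3245 for the combination, 1194 for the regimen difference and 3472 for either regimen.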
